A study of Rattus norvegicus with 9 samples.

How the data were processed

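Rat cortical neurons in primary culture were transduced with lentivirus carrying a short hairpin RNA, and poly(A) RNA was sequenced from 9 samples, 3 in each of 3 groups. A short hairpin RNA is processed by the cell into a small interfering RNA that lowers the level of its target transcript. The groups were shControl, shPum2 (aimed at Pumilio2) and shStau2 (aimed at Staufen2). Neurons were harvested after 14 days in culture, the last 4 of them after transduction, per the labels' protocols. RNA was extracted with TRIzol and made into libraries with a directional kit that records the strand of the transcript, per the labels' protocols.

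The deposited values are raw counts of reads per gene, 1 file per sample, with no normalization. Reads were demultiplexed with bcl2fastq 2.19.1.403 and aligned with STAR 2.6.1a, per the submitters' processing notes. The genome build, the annotation release and the strand setting used in counting are not given in the sources used here. Each file holds 32883 rows with an Ensembl rat gene identifier and 4 rows that name no gene, which give the unmapped, multimapping, no-feature and ambiguous reads. These 4 rows were kept out of library sizes and tests. They hold nearly all of the reads, since gene rows take between 1.76% and 2.14% of the reads listed in a library. No-feature reads take between 86.0% and 88.1%. Gene counts sum to between 779386 and 979550 per library, and that total, not the 42536675 to 47767757 reads listed, is the depth behind every value. Whether the reads assigned to genes came from the strand of the mRNA or from the opposite strand is not known from the sources used here, so a count below is a count of reads assigned to a gene on the counted strand.

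The files give identifiers with no gene symbols. The name table used here (rat assembly GRCr8) carries symbols, but its column for Ensembl identifiers was empty in the copy used, so it matched 0 of the 32883 identifiers, and no annotation or sequence was used. The level of Pum2 and Stau2 in each library, the 30 gene lists fixed before the data were examined, the Pumilio motif analysis and all gene symbols are therefore not reported. The rule for named genes, fixed at the same time, required a symbol. Its size criterion was applied without that condition, and at most 2 identifiers that rose and 2 that fell are printed over the whole study. They are the largest changes among genes with an adjusted p under 0.05, a mean of at least 5 CPM over the 9 libraries and no overlap between the libraries of the groups compared.

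Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (5697 genes, which hold 96.0% to 97.7% of the gene counts of a library), scaled with TMM factors and fitted with a quasi-likelihood negative binomial model with 1 coefficient per group and all 9 libraries in the fit. Tests were two-sided and adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. CPM is the count of a gene relative to the filtered gene counts of its library, after TMM scaling. Fold changes are shPum2 minus shControl, shStau2 minus shControl and shPum2 minus shStau2 on the log2 scale, and the standard error of each was taken from its quasi-likelihood F statistic. Principal components were computed on log2 CPM with a prior count of 2. A gene with 0 counts in a group was compared through a floor of 3 counts over the 3 libraries of the group. A group with 1 to 3 counts was compared by a ratio with an exact 95% interval from the binomial distribution. Both cover counting error only.

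The model was tested on simulated data with 200 genes changed by known factors. Counts were drawn gene by gene, with no structure of the samples that genes share. In the shPum2 against shControl setting (5466 genes tested) it called 13.4% of 2-fold, 77.6% of 4-fold and 93.9% of 8-fold changes. In the shStau2 against shControl setting (5447 genes) it called 13.4%, 85.1% and 92.4% of them. In the shPum2 against shStau2 setting (5424 genes) it called 10.4%, 79.1% and 86.4% of them. Of the calls made in these settings, 4.65%, 5.93% and 6.4% were of unchanged genes, in the same order.

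No 2 libraries of a group were duplicates, since the chi-square statistic per degree of freedom between their counts lay between 4.14 and 15.1 over genes with 10 or more counts in the pair. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these samples, which may be in part technical. The fit had no block for the replicate number. Alternatives were RLE and upper-quartile factors, no filter, a filter of 5 CPM in 3 libraries (planned as stricter, though it kept 8857 genes), DESeq2 1.42.0, voom in limma 3.58.1, fits of only the groups compared, the replicate number as a block, a minimum log2 change of 0.5 and each library left out in turn.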

Results

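Gene expression was measured by RNA sequencing in rat cortical neurons 4 days after transduction with a control hairpin or with a hairpin aimed at Pumilio2 or Staufen2, which are RNA-binding proteins of neuronal RNA granules. Each group held 3 libraries. Libraries listed 42536675 to 47767757 reads each, but only 779386 to 979550 of them per library were assigned to genes. The share assigned was 1.99% ± 0.20 in shControl, 1.94% ± 0.16 in shPum2 and 1.87% ± 0.047 in shStau2 (mean ± SD, n = 3 each). Of the reads placed at 1 site in the genome, 97.6% to 98.0% met no annotated feature on the counted strand. The strand of the counted reads relative to the mRNA is not known, which limits every gene value given here. Between 11567 and 13510 genes had at least 1 count in a library and between 4312 and 5854 had 10 or more. Both numbers were lowest in shStau2 replicate 3.

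**Figure D1:**
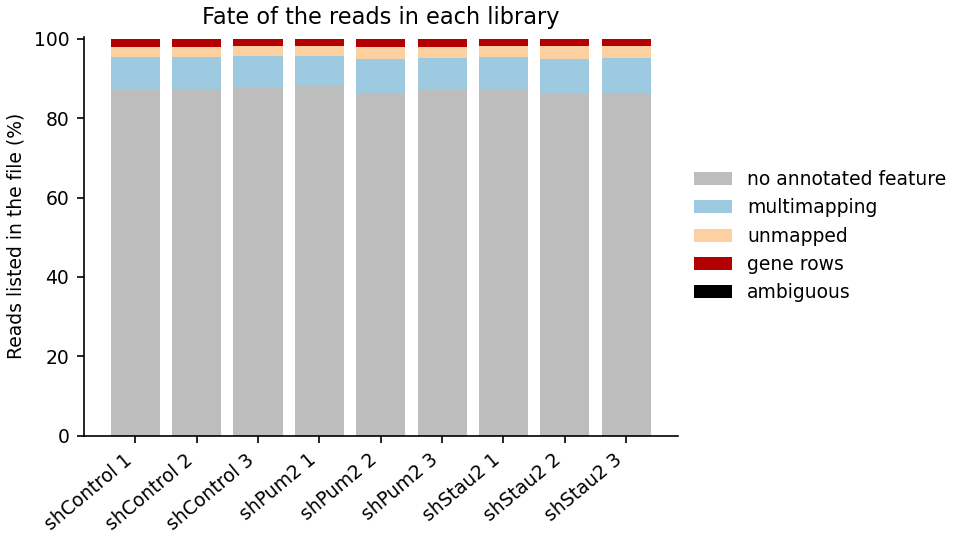
Stacked bars give the share (%) of the reads listed in each of the 9 libraries that met no annotated feature, were multimapping or unmapped, were assigned to gene rows, or were ambiguous. Gene rows take between 1.76% and 2.14% in the libraries of all 3 groups, and the ambiguous share, at most 0.0255%, is too small to see.

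A single gene took a large part of the gene counts in every library. Its share was 24.3% ± 5.4 in shControl, 19.5% ± 4.2 in shPum2 and 14.9% ± 4.7 in shStau2 (SD, n = 3 each). Its fitted log2 difference from shControl was -0.37 (SE 0.31) in shPum2 and -0.77 (SE 0.31) in shStau2, and neither passed the edgeR quasi-likelihood test (adjusted p = 0.999 and 0.36). The 10 most abundant genes together took 27.4% to 40.4% of the gene counts.

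The shStau2 libraries separated from the rest on the second principal component, which carried 20.8% of the variance. They lay between -27.4 and -19.9 on it, and the shControl and shPum2 libraries between 7.44 and 16.1. The first component carried 37.5% of the variance and did not follow the groups. On it shStau2 replicate 3 lay at 50.4, shPum2 replicates 2 and 3 at 16.9 and 21.1, and the other 6 libraries between -23.1 and -2.05. The mean Spearman correlation of shStau2 replicate 3 with its own group, across genes, was 0.729, against 0.808 to 0.867 for the other 8 libraries.

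**Figure D2:**
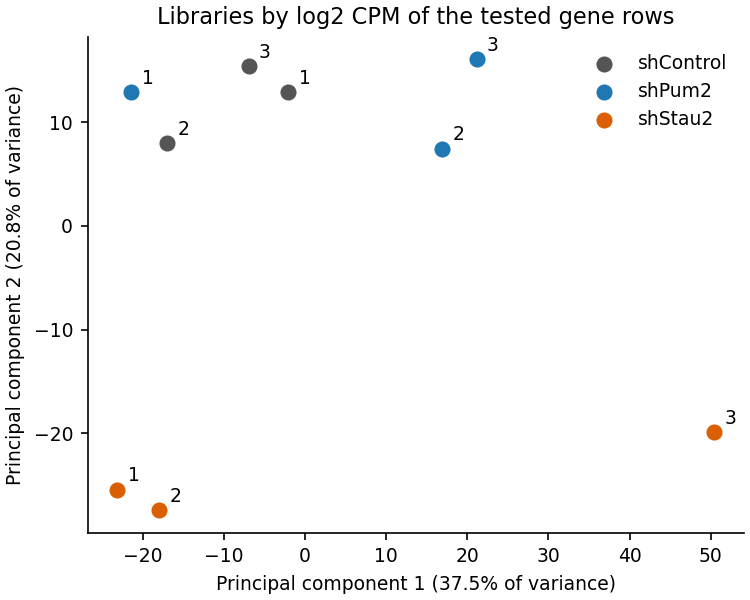
Each point is 1 of the 9 libraries, numbered by replicate, placed by its first and second principal components (37.5% and 20.8% of the variance) of log2 CPM over the 5697 genes tested. The 3 shStau2 libraries lie below the others on the second component, and shStau2 replicate 3 lies far from its group on the first.

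The first comparison asked which transcripts changed when Pumilio2 was targeted. Of 5697 genes, 1 rose and none fell in shPum2 against shControl (edgeR quasi-likelihood test, adjusted p under 0.05). The gene that rose, ENSRNOG00000052063, was nearly absent from the control libraries, with 2 counts in all 3 together and 0.776 ± 0.672 CPM (SD, n = 3). It reached 214 ± 11.2 CPM in shPum2 (n = 3), with 171 to 199 counts in each library. The ratio was 264, with a 95% counting interval of 72.7 to 2185, and the adjusted p was 3.53e-06. In shStau2 the same gene stood at 6.61 ± 4.92 CPM (n = 3), from 16 counts, which was not past the threshold against shControl (log2 difference 2.78, SE 0.86, adjusted p = 0.18). The median absolute log2 difference between shPum2 and shControl over all genes tested was 0.24, below the median standard error of 0.40, and the groups did not overlap for 8.48% of genes, where chance gives 10%. At an unadjusted p under 0.05 there were 112 genes, or 1.97% of those tested, where unchanged genes with evenly spread p-values would give a share of 0.05. The count of 112 depended on single libraries. It was 363 of 6226 without shPum2 replicate 1, 74 and 71 without shPum2 replicate 2 or 3, and 258 of 6334 without shStau2 replicate 3. It was 98 with limma-voom and 447 with limma-voom and library quality weights. In simulated data of this depth and spread, with 200 genes changed, 13.4% of 2-fold changes were called. Benjamini-Hochberg adjustment is stricter where fewer genes change, so this share may be too high for a comparison with 1 call. The simulated counts were drawn gene by gene, without the structure across samples seen on the first principal component. The count of 1 became 2 without shPum2 replicate 1 or 3, 3 with DESeq2, 8 with no filter on low counts and 4 without shStau2 replicate 3 in the shared fit. It was 3 with 5 CPM in 3 libraries, 4 when only these 2 groups were fitted and 2 with limma-voom and library quality weights. ENSRNOG00000052063 was among the calls each time.

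The second comparison asked the same of Staufen2. In shStau2 against shControl 44 genes fell and 6 rose out of 5697 (edgeR quasi-likelihood test, adjusted p under 0.05), and 647 genes had an unadjusted p under 0.05 (1023 of 6334 without shStau2 replicate 3, 606 with limma-voom and 1064 with limma-voom and library quality weights). Each of the 50 changed by at least 1.05 on the log2 scale, and in each the libraries of the 2 groups did not overlap, which held for 16.9% of all genes tested, where chance gives 10%. The median log2 change was -1.94 among the genes that fell, also with the 1 gene at 0 counts in shStau2 set at its bound, and 1.92 among those that rose. Of the genes that fell, 19 fell by 2 or more log2 units, and of those that rose 3 rose by as much. The genes that fell reached into the most abundant class: 3 of them had a mean of 1000 CPM or more, a class of 131 genes in which none rose, 9 had 100 to 1000 CPM, 30 had 10 to 100 CPM and 2 had less. Of the genes that rose, 3 had 100 to 1000 CPM and 3 had 10 to 100 CPM. With only 6 that rose out of 5697, finding none in a class of 131 is no contrast between the directions.

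By fitted change ENSRNOG00000042458 and ENSRNOG00000021087 fell furthest, both from few counts. ENSRNOG00000042458 had 34 counts over the control libraries (13.4 ± 6.99 CPM, SD, n = 3) and 0 in each of the 3 shStau2 libraries. Against a floor of 3 counts over the group it was at least 11.6-fold lower (edgeR adjusted p = 0.023). ENSRNOG00000021087 fell from 15.6 ± 4.20 CPM to 0.710 ± 1.23 CPM (n = 3 each), with 38 counts against 2, a ratio of 19.4 with a 95% counting interval of 5.02 to 166 (adjusted p = 0.019). Both of the shStau2 counts were in replicate 1, and without that library the fitted log2 change went from -4.07 to -6.68, a value that is no bound because the libraries left were at 0. ENSRNOG00000028569 rose from 4.06 ± 0.612 CPM to 23.5 ± 10.9 CPM (n = 3 each), a log2 change of 2.48 (SE 0.54, adjusted p = 0.041). In shPum2 these 3 genes stood at 11.8 ± 6.73, 13.5 ± 2.55 and 5.0 ± 1.19 CPM (n = 3 each), none of them past the threshold against shControl (adjusted p = 0.999 for each). All 3 rest on few counts, and over the alternatives their adjusted p ran from 9.08e-06 to 0.18, from 0.00016 to 0.15 and from 0.0056 to 0.33 in the order given, each highest with limma-voom. The count of 50 depended on single libraries: it was 16, 24 and 23 without shControl replicate 1, 2 or 3, 23 and 16 without shStau2 replicate 1 or 2, and 112 without shStau2 replicate 3, when 28 genes rose, 84 fell and 49 of the 50 were kept. It was 30 when only these 2 groups were fitted, 82 with DESeq2, 89 with no filter, 40 with limma-voom and 187 with limma-voom and library quality weights.

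**Figure D3:**
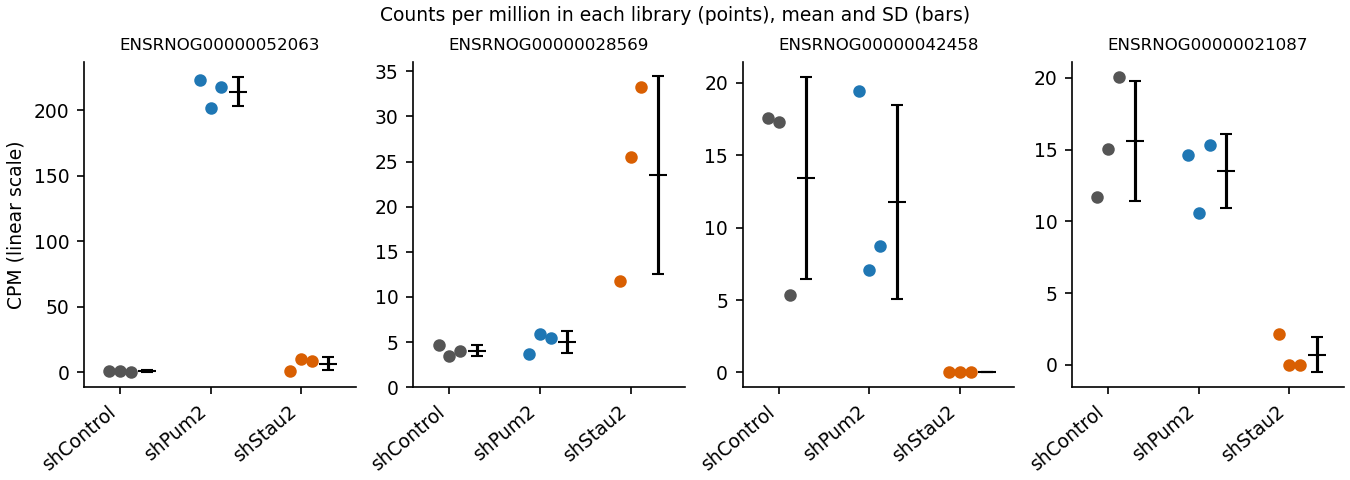
Points give the CPM (linear scale) of 4 genes in each library of shControl, shPum2 and shStau2, with the mean and SD of the 3 libraries beside them. ENSRNOG00000052063 stands at 214 CPM in shPum2 against 0.776 in shControl, and ENSRNOG00000042458 is at 0 in all 3 shStau2 libraries.

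The third comparison set the 2 hairpin groups against each other. The control values do not enter this difference, but the control libraries stay in the fit that sets the filter and the spread. Between shPum2 and shStau2 46 genes differed, 39 higher in shPum2 and 7 higher in shStau2 (edgeR quasi-likelihood test, adjusted p under 0.05). Of the 44 genes that fell in shStau2 against shControl, 26 were also higher in shPum2 than in shStau2, and of the 6 that rose 3 were also lower in shPum2. Both comparisons use the same shStau2 libraries, so this overlap is in part built in and is not independent support. No expected overlap was simulated. ENSRNOG00000052063 was higher in shPum2 than in shStau2 by 5.02 on the log2 scale (SE 0.47, adjusted p = 4.11e-05). ENSRNOG00000042458, with 30 counts in shPum2, was at least 9.76-fold higher there than in shStau2 (adjusted p = 0.037), and ENSRNOG00000021087 was higher by a ratio of 17.1 with a 95% counting interval of 4.39 to 147 (adjusted p = 0.035). ENSRNOG00000028569 did not pass (log2 difference -2.18, SE 0.52, adjusted p = 0.057). Of the 46 genes 16 were called in neither comparison with shControl. The count was 15 and 10 without shPum2 replicate 2 or 3, 10 and 11 without shStau2 replicate 1 or 2, and 270 without shStau2 replicate 3, when the split was 144 higher and 126 lower in shPum2 in place of 39 and 7. It was 10 when only these 2 groups were fitted, 30 with 5 CPM in 3 libraries, 82 with DESeq2, and 103 with no filter. It was 36 with limma-voom (31 higher and 5 lower) and 318 with limma-voom and library quality weights (169 higher and 149 lower). A regrouping of the same 6 libraries across the groups gave 639.

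No gene was called in both comparisons with shControl by edgeR. Independent lists of these lengths would share 0.00105 higher calls, and 50 simulations of unchanged groups against the same controls gave a mean of 0.02 shared calls, with at most 1. An unadjusted p under 0.05 in both comparisons was found for 34 genes, 31 of them with the same sign, where the simulations gave 51.0 ± 6.70 and 50.8 ± 6.69 (SD). The observed lists held 112 genes for shPum2 and 647 for shStau2, and the lengths of the simulated lists were not kept. The overlaps may thus rest on lists of unlike length. They do not show that the hairpins shared fewer genes than unchanged groups would. DESeq2 and the fit with no filter gave 1 and 2 genes called in both with the same sign, leaving out shPum2 replicate 1 gave 1, and limma-voom gave 0 without and 1 with library quality weights. Among the 44 genes that fell in shStau2 the median log2 difference in shPum2 was -0.20, with 37 below 0, and among the 6 that rose it was 0.28, with 5 above 0. Both comparisons use the same control libraries. In these simulations the 44 genes with the smallest p among those lower in shStau2 included 39.2 ± 2.09 (SD) that were below 0 in shPum2 too, and of the 6 among those higher 5.84 ± 0.37 were above 0. The simulated genes had no change and were picked by noise alone, that of the shared controls included. Genes called in the data were not picked in this way, so the simulated counts are not the numbers expected of them. Across genes, which are not independent replicates, the log2 differences of the 2 comparisons had a Pearson correlation of 0.34 and a Spearman correlation of 0.34. In the same simulations the Pearson correlation was 0.50 ± 0.012 (SD). The observed covariance was 0.0794 and the simulated one 0.0973 ± 0.0034. Without shStau2 replicate 3 the observed Pearson correlation was 0.16 and the covariance 0.0467, against 0.45 ± 0.012 and 0.0816 ± 0.0032 in 50 simulations with the spread of the 8 libraries left. Both simulations gave the controls the spread estimated over all groups, while the mean Spearman correlation within a group was 0.861 to 0.867 for the control libraries and 0.729 to 0.848 for the others, so the simulated values are not a measure of these controls alone. With 3 controls, a split that leaves 2 or more libraries on each side was not possible, so part of any agreement may come from the shared controls.

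**Figure D4:**
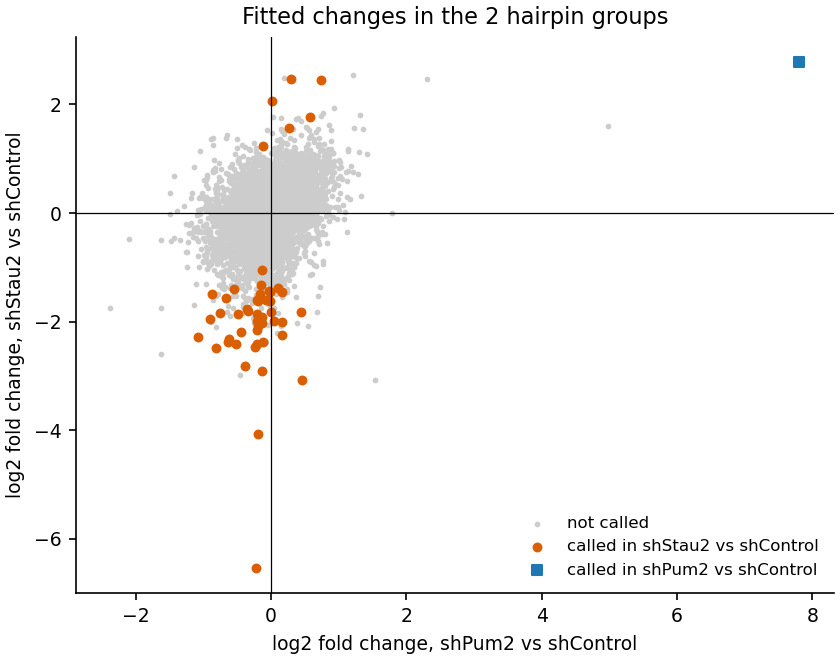
Each point is 1 of the 5697 genes tested, with its log2 fold change in shPum2 against shControl (x axis) and in shStau2 against shControl (y axis). The 50 genes called in shStau2 spread along the y axis and the 1 gene called in shPum2 stands alone at the right, with none called in both.

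The reads assigned to no gene were compared between groups as well. Multimapping reads were 7.99% ± 0.15 in shControl and 8.64% ± 0.37 in shStau2 (SD, n = 3 each), and unmapped reads were 2.56% ± 0.064 and 2.91% ± 0.22. Every shStau2 library was above every control in both measures, at the smallest p that 3 against 3 libraries allow (exact permutation test, two-sided, p = 0.1, Benjamini-Hochberg adjusted p = 0.4 over 12 tests). The shPum2 shares overlapped those of shControl.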

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

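The tests on the share of reads in genes, on the labelling of shStau2 replicate 3 and on ENSRNOG00000052063 were chosen after the result was seen. The tests of depth and of low-count genes were set before. No group was large enough to test a single library as an outlier.

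Of the genes named above, 3 differed between the hairpin groups in the direct test of shPum2 against shStau2: ENSRNOG00000052063 by 5.02, ENSRNOG00000042458 by 6.32 and ENSRNOG00000021087 by 3.87 on the log2 scale, the last 2 being fitted values of genes with 0 and 2 counts in shStau2. Outside the gene rows, all 3 shStau2 libraries lay above every control, with means of 8.64% multimapping, 2.91% unmapped and 0.0232% ambiguous reads. None of these passed a test (exact permutation test, p = 0.1, the smallest possible, Benjamini-Hochberg adjusted p = 0.4 for each). The shares were not particular to shStau2. They were 8.67%, 2.87% and 0.0255% in shPum2 replicate 2, above the 8.22%, 2.71% and 0.0251% of shStau2 replicate 1.

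ENSRNOG00000052063 went from 2 counts in the controls to 553 in shPum2, and one aberrant shPum2 library is argued against, because the highest adjusted p without any 1 of the shPum2 libraries was 1.32e-05. A candidate explanation that stays open is reads from the shPum2 vector that align to this gene. Its 16 counts in shStau2 against 2 in the controls differed by more than counting error alone (exact binomial p = 0.00133), but the libraries overlapped (lowest shStau2 library 1.07 CPM, highest control 1.17 CPM) and edgeR did not call it (adjusted p = 0.18). The 16 counts are 2.89% of those in shPum2. Reads misassigned between libraries, not measured here, could give them, but would have to reach the shStau2 libraries more than the control libraries. A response of the neurons to a lower level of Pumilio2, which was not measured, or to an unintended target of the hairpin, also stays open and was not tested.

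Only about 2% of the reads were assigned to genes, and genomic DNA as the source of the other reads is argued against, since it would reach nearly every gene and 48.4% of genes stayed at 0 over all 9 libraries. Chromosome names that match the annotation for few chromosomes are argued against as well, since 51.6% of genes held a count. Counting on the strand opposite to the mRNA is an explanation that stays open. At least 97.6% of uniquely placed reads outside any feature is the value it needs. The same value defines the pattern, however, and the sense counts were not used here. The genome build and the annotation release are not given, so whether they play a part was not tested. If the opposite strand was counted, the values may mix antisense and neighbouring transcription with a small remainder of sense reads. The changes above may then not be changes of the named mRNA. No biological explanation was tested.

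In shStau2 replicate 3 the mean Spearman correlation with its group was 0.729. Lower depth is argued against, because that library had 803406 gene counts, more than shControl replicate 3 (783538) and shPum2 replicate 1 (779386). The mean correlations of those libraries with their own groups were 0.861 and 0.808. After thinning every library to 779386 counts the value was 0.727 against 0.805 or more in the other 8. The thinning removed few counts from shStau2 replicate 3, so it could change little. Background reads on genes with few counts are argued against, because over the 845 genes with a mean of 100 CPM or more it was 0.77 against 0.864 or more. A library wholly from other neurons is argued against by the 112 genes called without it. Over them it moved by a median of 0.90 log2 units in the direction of the other shStau2 libraries, with 94 genes in that direction. The highest shPum2 library reached 0.17 and the highest control, shControl replicate 2, reached 0.23. Replicates 1 and 2 of shStau2, from which the genes were called, reached 1.53 and 1.44. The Spearman correlation of replicate 3 was 0.852 and 0.841 with shPum2 replicates 3 and 2, against 0.718 and 0.740 with shStau2 replicates 1 and 2. A library only partly from shStau2 neurons was not tested and is not excluded. Fewer genes were detected in shStau2 replicate 3 than in any other library, though its gene counts were not the lowest. It had 11567 genes with at least 1 count, against 12390 to 13510 in the other 8. With 10 or more counts it had 4312, against 4691 to 5854. The cause of these low numbers was not tested. A difference between cultures or in preparation stays open, since the labels name no batch.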

How the results depend on the processing

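The fits with limma-voom and library quality weights (weighted voom), without the most abundant gene and without shStau2 replicate 3 in the shPum2 comparison were chosen after seeing the data. The cause was not tested for any change below. Leaving out a library changed the sample size, the estimated spread and the genes tested together, and these were not separated. For shPum2 against shControl the count of 1 became 3 with the replicate block, 8 with no filter, 3 with 5 CPM in 3 libraries, 3 with DESeq2, 4 with only the 2 groups compared, 4 without shStau2 replicate 3 in the shared fit and 2 with weighted voom, and lay between 1 and 2 when 1 library of these 2 groups was left out. For shStau2 against shControl the count of 50 became 83 with the replicate block, 89 with no filter, 82 with DESeq2, 30 with only the 2 groups compared and 187 with weighted voom, and ran from 16 to 112. For shPum2 against shStau2 the count of 46 became 81 with the replicate block, 103 with no filter, 30 with 5 CPM in 3 libraries, 82 with DESeq2, 10 with only the 2 groups compared and 318 with weighted voom, and ran from 10 to 270 when 1 library was left out. The count of 0 genes shared by both hairpins became 1 with the replicate block, 2 with no filter, 1 with DESeq2 and 1 with weighted voom, and lay between 0 and 1 when 1 library was left out. RLE and upper-quartile factors, unweighted voom (1, 40, 36 and 0 genes), the minimum log2 change of 0.5 and leaving out the most abundant gene moved no count by over 1.5 times. Of the named genes, ENSRNOG00000052063 kept its direction and its call in all 17 alternatives run on it (adjusted p 8.00e-36 to 0.048). ENSRNOG00000028569, ENSRNOG00000042458 and ENSRNOG00000021087 kept their direction in all of theirs, and their call was lost in 8 of 15, 5 of 14 and 4 of 14 of them. The groups share replicate numbers, but deviations from the group means correlated above 0.1 in only 5 of the 9 same-number pairs (-0.25 to 0.53), so the numbers were not taken to pair the samples. In the replicate block, 50 of the 50 shStau2 calls were kept, and 5 of 9 libraries correlated best with a library of their own number, a hint from the data, not the design. DESeq2 gave no adjusted p for the 3 shStau2 genes named, and ENSRNOG00000042458 and ENSRNOG00000021087 did not pass the filter when only the 2 groups were fitted. The knockdown check, the gene lists and the Pumilio motif analysis, with all their alternatives, were not run because the identifiers were not matched to symbols and no transcript sequences were used here. With 200 genes changed, 13.4% of simulated 2-fold changes were called for each hairpin against shControl, a share that may be lower where fewer genes change. Depth and spread were not separated.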

Other observations

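The number of splits was fixed by the design, and the description of the first component and the coefficient of variation without shStau2 replicate 3 were chosen after the result was seen. With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. For shPum2 against shControl 1 of the 10 splits, the real one, gave as many genes as the real 1, and the highest other gave 0. For shStau2 against shControl 1 of the 10 splits, the real one, gave as many as the real 50, and the highest other gave 0. For shPum2 against shStau2 2 of the 10 splits gave as many as the real 46, and the highest other gave 639.

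The split with 639 genes set shPum2 replicate 1 with shStau2 replicates 1 and 2 against shPum2 replicates 2 and 3 with shStau2 replicate 3. It follows the first principal component and points to a structure of the samples that crosses the groups and that the labels do not name. The replicate numbers give it in part. The replicate 1 libraries of the 2 groups lay on the same side, and so did the replicate 3 libraries (correlations of deviations 0.528 and 0.484). The replicate 2 libraries were divided. On the first component the shControl libraries lay between -17.0 and -2.05, between the 2 sides of the split. The number of genes with at least 1 count also differed between the sides. It was 12913 in shPum2 replicate 1 and 13510 and 13065 in shStau2 replicates 1 and 2. In shPum2 replicates 2 and 3 it was 12560 and 12587, and in shStau2 replicate 3 it was 11567. The shControl libraries had 12579, 13030 and 12390, not all between the sides. Whether this number and the structure have 1 cause was not tested. Fitting without shStau2 replicate 3 lowered the common biological coefficient of variation from 29.0% to 22.8%.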
